A study of Mus musculus with 5 samples.

How the data were processed

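RNA from 5 end-stage mouse medulloblastomas was hybridised to Illumina mouse whole-genome bead arrays, 1 array per tumour. Per the labels' protocols, RNA was taken up in Trizol, purified on RNeasy columns with DNase treatment and checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The authors deposited a probe signal intensity for each of 45281 probes on each array, which is not normalized per the file headers. Beside each signal the authors deposited a detection p-value per probe and array, per the file headers. The deposited table of processed values was on a log2 scale, as found by setting it against the signals. Each of its columns ranked the probes as the signals of the same array did (rank correlation 1), and its sorted values differed from the log2 of the mean sorted signals by at most 0.00249. It therefore held quantile-normalized log2 signals with no background correction. The scanner and the software behind the signals were not given in the sources used here.

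Tumours were grouped by the genotype in the labels: 3 MyoD+/+;SmoA2 and 2 MyoD+/-;SmoA2. The labels name 5 tumours and do not say whether each came from its own mouse, so p-values measure the spread between these samples. Probes were named through the platform annotation, with symbols updated through Entrez identifiers from a RefSeq gene table (assembly GRCm38.p6), which was used for names, chromosomes and gene order only. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 were unnamed here. Of the named probes, 34807 matched the RefSeq table, which changed 0 symbols.

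Signals were background-corrected and normalized with neqc in limma 3.58.1 (R 4.3.3), which fits a normal-exponential model with negative controls inferred from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. Probes with a detection p under 0.05 on at least 2 of the 5 arrays were kept (18675 probes, 15899 of them with 1 symbol). Each gene was represented by its probe with the highest mean level over all 5 arrays, which left 10474 genes. Among these, 3792 had more than 1 probe that passed. Of the 95 genes chosen for naming, 28 had more than 1 probe, and in 5 of these the probes had opposite signs. Genotypes were compared with limma (lmFit and eBayes, two-sided) with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences are MyoD+/- minus MyoD+/+ on the log2 scale with their standard error (SE), and intervals are 95% intervals of the fit.

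A total of 22 gene lists were fixed before the data were examined. They covered myogenic regulators, muscle structural genes, the hedgehog, Notch and Wnt pathways, granule neuron precursors, granule neuron differentiation, proliferation, p53 targets and apoptosis, hypoxia and glycolysis, interferon response, immediate early genes and sex-linked genes. Cell type lists covered astrocytes, oligodendrocytes, microglia and macrophages, endothelial and mural cells, fibroblasts and meninges, red blood cells, Purkinje and other cerebellar neurons, choroid plexus and ependyma, and T and B lymphocytes. Each list was compared with all other genes by camera with a preset correlation between genes of 0.01, and adjusted over the 22 lists. Camera with a correlation estimated for each list and fry were run as alternatives. The number of members past the threshold was counted over all genes tested and also adjusted over the list alone.

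The rule for named genes was also fixed before the data were examined. It took Myod1, the genes past the threshold, and, where fewer than 10 passed in a direction, the 10 of smallest unadjusted p, named as not passing. It added the myogenic regulators that passed the detection filter, the 6 muscle structural genes and the 3 genes of every other list with the smallest unadjusted p, and 5 hedgehog-related genes (Gli1, Ptch1, Mycn, Ccnd1 and Atoh1) where detected. A gene with no array of a group above background has only a bound there. For such a gene the brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest detected level and the gene's own, and the ratio is given as "at least". The brighter group's mean keeps the values of any array not above background. The ratio concerns the group means and carries no spread between tumours.

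Alternatives were quantile normalization without background correction, median scaling, an offset of 50, the authors' processed values, no filter and a stricter filter (detection p under 0.01 on every array of a group), the mean of a gene's probes, every probe on its own, a mean-variance trend with robust estimation, array weights, the letters in the sample titles as a block, and leaving out each tumour in turn. Only MyoD+/+ tumour 1 carries the letters AI, so the block on title letters takes it out of the genotype difference. The differences under that block therefore equal those without MyoD+/+ tumour 1. A block for the array slide was not run, because the columns name no slide. The methods were tested on simulated data with 3 against 2 arrays and 10474 genes, of which 200 changed, in 20 data sets. They recovered 65.1% of genes changed 2-fold and 99.4% of genes changed 4-fold, and 6.99% of the genes called were unchanged. The simulated noise was normal and independent between genes, so these shares do not give the power for the real tumours. Among the real genes, Gdpd3 differed by -2.70 (log2) and did not pass (limma adjusted p = 0.398). Camera with the preset correlation called 4% of unshifted lists of 16 genes at an unadjusted p under 0.05. That share was 33.9% where the genes of an unshifted list were correlated at 0.35, and 2.38% with the estimated correlation. The number of arrays limits the precision: the median SE of a difference was 0.20 and the median 95% interval reached 0.47 to either side, a fold of 1.39.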

Results

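Gene expression was measured in 5 end-stage medulloblastomas of mice that carry SmoA2, an activated form of the hedgehog receptor component Smoothened that drives tumours of the cerebellum. Of these, 3 had both copies of the myogenic transcription factor gene Myod1 (MyoD+/+;SmoA2, tumours 1 to 3) and 2 had a single intact copy (MyoD+/-;SmoA2, tumours 1 and 2). The median probe signal was 145.2, 133.6 and 148.1 in the MyoD+/+ tumours and 145.3 and 146.5 in the MyoD+/- tumours, on the arrays' linear scale. Between 37.0% and 39.9% of the 45281 probes were detected on each array, with the fewest (16767) in MyoD+/+ tumour 2 and the most (18055) in MyoD+/- tumour 2. Across the 10474 genes tested, Pearson's r between arrays ranged from 0.965 to 0.984. These correlations are across genes, which are not independent replicates.

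The series asks whether the canonical muscle differentiation programme takes part in the effect of losing MyoD in these tumours. The muscle regulators and muscle structural genes did not pass the test as lists, and no member of either passed singly. Myod1 itself was above background in all 5 tumours. Its level was 7.25, 6.38 and 7.08 in the MyoD+/+ tumours and 6.31 and 6.67 in the MyoD+/- tumours (log2). The difference was -0.41 ± 0.28 (SE, n = 3 and 2; limma adjusted p = 0.957), with a 95% interval from -1.08 to 0.26, and the groups overlapped. That interval includes a loss of 1 log2 unit, the most that a halved level would give, since the added offset makes such a loss smaller. The difference was -0.20 without background correction and with the authors' processed values. The position of the Myod1 probe relative to the altered part of the gene is not given in the sources used here, so this level may not check the genotype labels.

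Of 24 myogenic regulators, 22 had a probe and 12 passed the detection filter. Myf5, Pax3 and Pax7, which act at the start of the muscle lineage, were detected on 0 of the 5 arrays, and Myf6 on 1. A gene not detected here is not shown to be absent, since detection also rests on its probe. Pcna of the proliferation list and Tubb3 and Snap25 of the granule neuron differentiation list also fell below the filter, though most members of those lists passed it. Myogenin (Myog), the regulator of terminal muscle differentiation, was detected in 2 of the 3 MyoD+/+ and 1 of the 2 MyoD+/- tumours, at means of 5.28 ± 0.12 and 5.16 ± 0.12 (SD, n = 3 and 2). Among the 12 tested regulators, 5 were higher and 7 lower in the MyoD+/- tumours, with a median log2 difference of -0.01 (camera adjusted p = 0.735). The count past the threshold was 0 over all genes and 0 adjusted over the list alone. The Id genes, inhibitors of MyoD-type factors, stood at -0.50 ± 0.22 (Id1), 0.41 ± 0.26 (Id2) and -0.45 ± 0.22 (Id3) (log2 difference ± SE), none passing. Mef2c, a cofactor of MyoD that is also expressed in neurons, differed by 0.09 ± 0.29. The muscle cadherin Cdh15, which granule neurons of the cerebellum also express, differed by -0.17 ± 0.37.

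**Figure D1:**
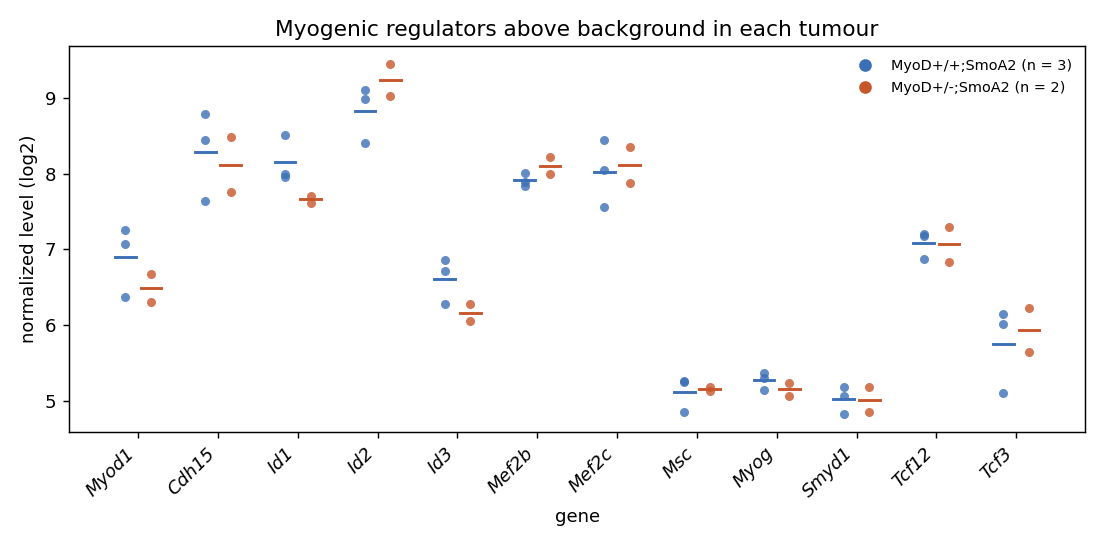
Normalized log2 level (vertical axis) of the 12 myogenic regulators that passed the detection filter (horizontal axis) in each tumour. Points are single tumours, blue for MyoD+/+;SmoA2 (n = 3) and orange for MyoD+/-;SmoA2 (n = 2), and short lines are group means; Myod1 lies at 6.90 and 6.49 on average, with overlapping tumours.

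The muscle structural list held 65 genes, of which 59 had a probe and 30 passed the filter. Of these, 12 were higher and 18 lower in the MyoD+/- tumours, and 0 passed over all genes or adjusted over the list alone. The median log2 difference was -0.05 and the mean 0.06, of opposite sign (camera adjusted p = 0.879, direction down). The mean was pulled up by Tnnc2, a fast-muscle troponin, at 2.47 ± 1.69 (SE). Tnnc2 stood at 4.92 in MyoD+/+ tumour 2, not above background, and between 10.04 and 11.95 in the other 4 tumours. The slow-muscle troponin Tnnt1 was not above background in either MyoD+/- tumour and was detected in 2 of the 3 MyoD+/+ tumours, at least 1.25-fold lower in MyoD+/- (limma adjusted p = 0.945). The embryonic light chain Myl4 differed by 0.41 ± 0.26 and the acetylcholine receptor subunit Chrnb1 by 0.28 ± 0.18. The sarcomere protein gene Ldb3 was at least 1.08-fold lower. Parvalbumin (Pvalb), which cerebellar interneurons also express, differed by -0.46 ± 0.31. The muscle creatine kinase Ckm and the myosin heavy chains Myh1, Myh4 and Myh7 were detected on 0 of the 5 arrays, which does not show that they are absent.

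Across the genome, the tumours of the 2 genotypes were alike at the resolution of 5 arrays. Of 10474 genes, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.398. At an unadjusted p under 0.05 there were 551 genes, 261 higher and 290 lower in the MyoD+/- tumours, where 523.7 are given by chance. On the same 10474 genes that count was 666 with array weights and 374 with a block on Xist signal. It was 879 with the letters of the sample titles as a block, which takes MyoD+/+ tumour 1 out of the difference and pairs the other tumours by letter. Leaving out MyoD+/+ tumour 1 with no block gave 529, so its removal alone does not give the higher count. The groups did not overlap in 20.9% of genes, against 20% by chance. The 95% interval excluded a 2-fold difference in both directions for 87.7% of genes. That share is on the normalized scale, whose added offset makes differences of dim genes smaller. Leaving out MyoD+/+ tumour 2 brought Gdpd3 past the threshold (1 gene, -3.01 ± 0.19, adjusted p = 0.0194), and leaving out MyoD+/+ tumour 3 brought Zdbf2 past it (1 gene, -2.97 ± 0.20, adjusted p = 0.0259). With a mean-variance trend and robust estimation, 2 genes passed (Gdpd3 and Mbp, both at an adjusted p of 0.0181).

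The genes with the smallest p, none of which passed, were led by Gdpd3, a phospholipid-metabolising phosphodiesterase. It stood at 8.53 ± 0.54 (SD, n = 3) in the MyoD+/+ tumours and at 5.83 ± 0.10 (SD, n = 2) in the MyoD+/- tumours, a difference of -2.70 ± 0.30 (SE). Zdbf2, a paternally expressed imprinted gene, was above background in all 3 MyoD+/+ tumours and in neither MyoD+/- tumour, at least 5.09-fold lower. Both differences were smaller with a larger offset and without background correction: Gdpd3 differed by -2.16 and Zdbf2 by -1.75 with an offset of 50, by -1.48 and -1.06 without background correction, and by -1.49 and -1.06 with the authors' processed values. Myelin basic protein (Mbp) differed by -1.29 ± 0.19 on its main probe and by -1.06 ± 0.26 and 0.10 ± 0.17 on its other probes. Also at the low end were Clic6 (-1.46), Iqsec3 (-1.10), Hhatl (-1.10), Ccdc92b (-0.85), Rbbp6 (-0.80) and Ssbp4 (-0.78), as log2 differences. Klk6, a serine protease of oligodendrocytes, was not above background in the MyoD+/- tumours on its main probe and at least 1.93-fold lower there. Its other probe gave a smaller difference of -0.40 ± 0.20. At the high end were Tecta (1.82 ± 0.30), Afap1 (1.32 ± 0.30), the neural progenitor filament nestin (Nes, 1.10 ± 0.22) and the spindle assembly factor Tpx2 (0.96 ± 0.20). Stag3 (0.87), Sncg (0.83), Rasgef1c (0.80) and Mbd2 (0.80) followed. Kdm5c and Cacybp were not above background in any MyoD+/+ tumour, and were at least 1.34-fold and 1.25-fold higher in MyoD+/-. Without background correction the differences were -0.98 (Clic6), -0.51 (Iqsec3), -0.35 (Hhatl), -0.26 (Ccdc92b), -0.36 (Rbbp6) and -0.48 (Ssbp4) at the low end, with Mbp at -1.23 and Klk6 at -0.33. At the high end they were 1.03 (Tecta), 0.53 (Afap1), 0.61 (Nes), 0.45 (Tpx2), 0.28 (Stag3), 0.41 (Sncg), 0.69 (Rasgef1c), 0.32 (Mbd2) and 0.26 (Cacybp). Other probes gave smaller differences of the same sign for Nes (0.65 ± 0.21), Rasgef1c (0.30 ± 0.24) and Rbbp6 (-0.34 ± 0.19). A different probe of Kdm5c gave -0.39 ± 0.22. That other probe stood for the gene without background correction and with the authors' processed values, where the difference was -0.13. The adjusted p of each of these genes other than Gdpd3 was 0.911 in limma.

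The lists that describe the tumour itself did not pass. Of the hedgehog pathway, 12 genes were tested, 8 higher and 4 lower, with a median log2 difference of 0.02 (camera adjusted p = 0.754). The hedgehog receptor gene Ptch1 differed by -0.14 ± 0.24 and the cyclin gene Ccnd1 by 0.14 ± 0.19, while Gli1, Mycn and Atoh1 fell below the detection filter in these arrays. Igf2, Ccnd2 and Sox18 differed by -0.49 ± 0.23, 0.28 ± 0.22 and 0.41 ± 0.32. Of 13 granule neuron precursor genes, 10 were higher and 3 lower (median 0.05, adjusted p = 0.735). Within that list Sox11 differed by 0.19 ± 0.17, Neurod1 by 0.41 ± 0.29 and Sox2 by -0.29 ± 0.16. Of 23 granule neuron differentiation genes, 14 were higher and 9 lower (median 0.12, adjusted p = 0.735), with Kcnd2 at 0.71 ± 0.35 and Gap43 at -0.37 ± 0.19. Of 30 proliferation genes, 21 were higher and 9 lower (median 0.09, adjusted p = 0.165). Examples were Tpx2, the mitotic kinase Plk1 at 0.40 ± 0.17 and Nusap1 at 0.32 ± 0.19. The p53 target and apoptosis list had 13 of 17 genes higher (median 0.06, adjusted p = 0.735), and its member of smallest p was the death receptor gene Tnfrsf10b at -0.90 ± 0.38. The Notch list (7 genes, median 0.16, adjusted p = 0.735) and the Wnt target list (7 genes, median 0.14, adjusted p = 0.580) had the members Nrarp at 0.47 ± 0.27 and Nkd1 at 0.29 ± 0.24. In each of these lists, 0 members passed over all genes and 0 passed adjusted over the list alone. The proliferation list came past the threshold without MyoD+/+ tumour 2 (median 0.17, adjusted p = 0.00510) or MyoD+/- tumour 2 (0.19, 0.00763) and with median scaling (0.15, 0.0257). These calls rest on the preset correlation: the list's estimated correlation was 0.51, and with an estimated correlation the adjusted p was 0.884, 0.634 and 0.858 in the same settings and 0.842 with all 5 tumours. The proliferation median was -0.03 without MyoD+/- tumour 1. The granule neuron differentiation list passed without MyoD+/- tumour 1 (0.20, adjusted p = 0.0328, or adjusted p = 0.959 with an estimated correlation), and its median was -0.21 without MyoD+/+ tumour 2 and -0.24 without MyoD+/- tumour 2.

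**Figure D2:**
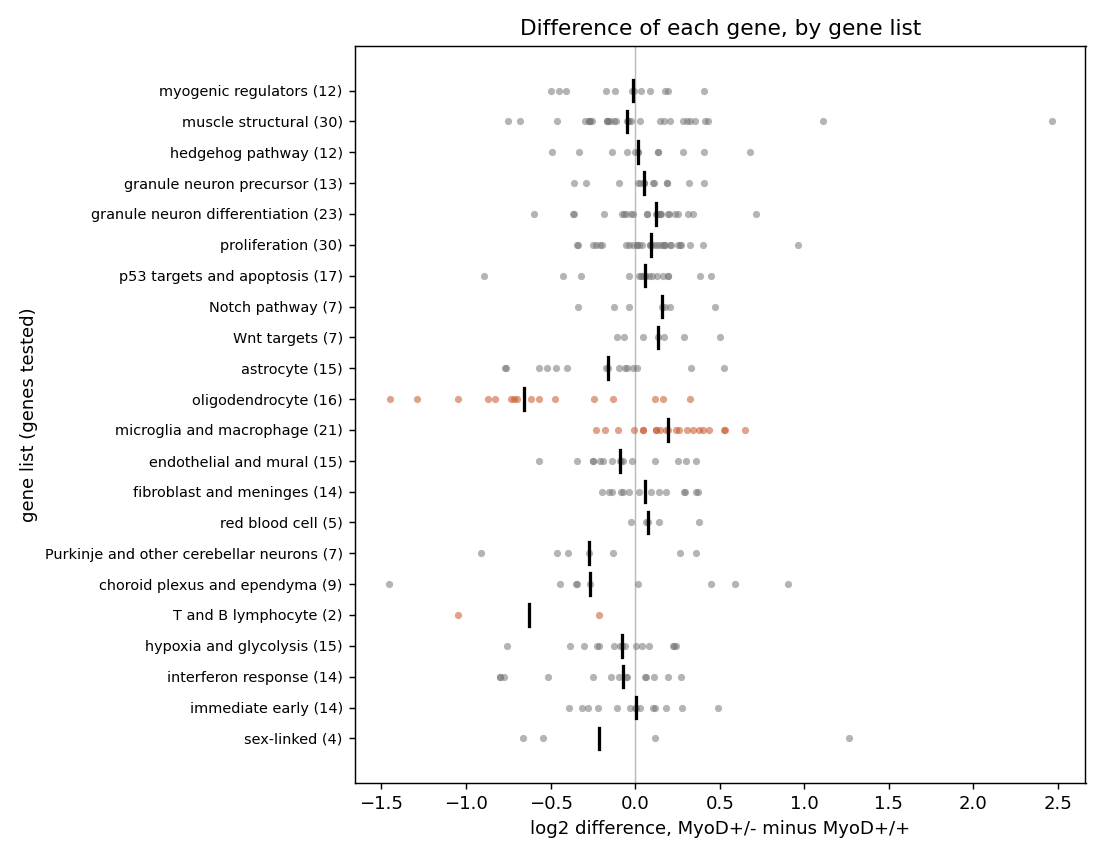
Log2 difference between genotypes, MyoD+/- minus MyoD+/+ (horizontal axis), of each tested gene in the 22 lists (vertical axis, genes tested in parentheses). Points are genes and black lines are list medians; orange marks the lists with a camera adjusted p under 0.05 at the preset correlation, among them the oligodendrocyte list with a median of -0.66.

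Most tested genes of oligodendrocytes, the myelin-forming cells of the brain, were lower on average in the MyoD+/- tumours. Of 16 genes tested, 13 were lower and 3 higher, with a median log2 difference of -0.66, a fold of 1.58 (camera adjusted p = 1.43e-08, or adjusted p = 0.842 with an estimated correlation). The size depends on the background correction and the offset added with it. The median was -0.48 with an offset of 50 and -0.30 without correction or offset, a fold of 1.23. It was -0.30 with the authors' processed values. At an unadjusted p under 0.05 there were 10 members, each lower, while 0 passed over all genes and 9 passed adjusted over the list alone. The myelin genes Mobp, Mbp and Mog differed by -1.45 ± 0.32, -1.29 ± 0.19 and -1.05 ± 0.23 (SE), and in 12 of the 16 genes the groups did not overlap. Over the 16 genes, the median level was 8.40, 8.34 and 7.57 in MyoD+/+ tumours 1 to 3. It was 7.73 and 7.69 in the MyoD+/- tumours, so MyoD+/+ tumour 3 lay below both. For 10 myelin genes of the list, the median level was 7.29 in MyoD+/+ tumour 3 and 6.56 and 6.79 in the MyoD+/- tumours. The estimated correlation between the list's genes was 0.35, and the camera p at that correlation was 0.0765 before adjustment over the lists. Fry, which asks whether a list's genes move one way on balance, gave an adjusted p of 0.579.

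**Figure D3:**
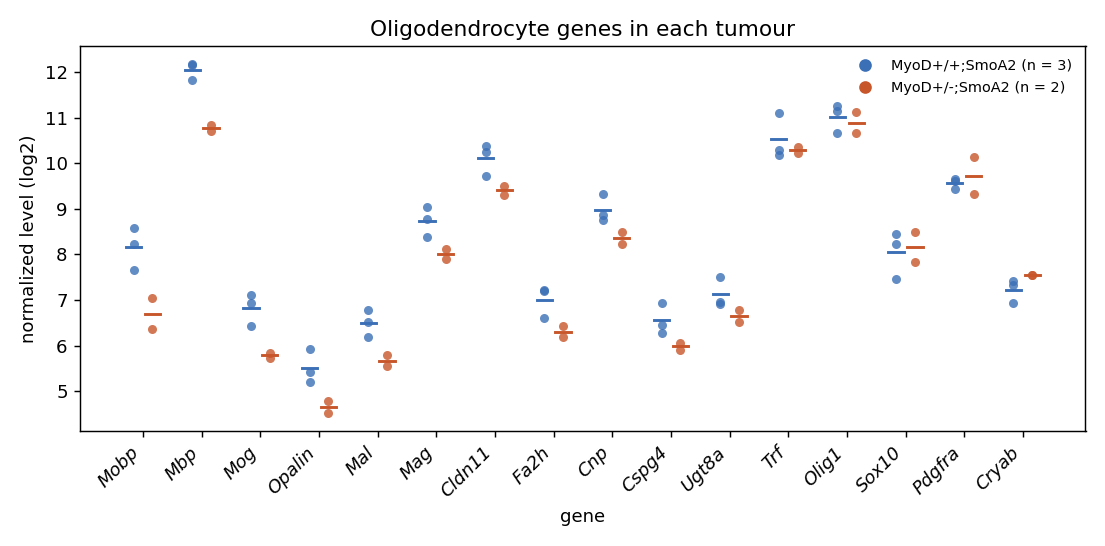
Normalized log2 level (vertical axis) of the 16 tested oligodendrocyte genes (horizontal axis, ordered by difference) in each tumour. Points are single tumours, blue for MyoD+/+;SmoA2 (n = 3) and orange for MyoD+/-;SmoA2 (n = 2), and short lines are group means. Mobp lies at 8.16 and 6.70 on average and the lineage gene Olig1 at 11.03 and 10.90.

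Genes of microglia and macrophages were slightly higher in the MyoD+/- tumours as a list. Of 21 genes, 17 were higher and 4 lower, with a median log2 difference of 0.20, a fold of 1.15 (camera adjusted p = 0.0101, or adjusted p = 0.842 with an estimated correlation). The MHC class II genes H2-Ab1 and Cd74 stood at 0.65 ± 0.25 and 0.53 ± 0.24 and the lysosomal gene Laptm5 at 0.43 ± 0.19 (SE), and 0 passed over all genes or adjusted over the list alone. Without background correction and with the authors' processed values the median was 0.11. Without MyoD+/+ tumour 3 the median was 0.13 and the adjusted p 0.289. The T and B lymphocyte list rested on 2 detected genes (median -0.63, camera adjusted p = 0.0371, or adjusted p = 0.842 with an estimated correlation). They were Thy1, which neurons also express, at -1.05 ± 0.25 and Cd8b1 at -0.21 ± 0.16. Of these, 0 passed over all genes and 1 (Thy1) passed adjusted over the list alone. That list no longer passed without MyoD+/+ tumour 1 or 2 or MyoD+/- tumour 1 (adjusted p = 0.117, 0.0841 and 0.109).

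Other cell types did not pass as lists. Of 15 astrocyte genes, 12 were lower (median -0.16, camera adjusted p = 0.109), with Ntsr2 at -0.77 ± 0.24, the gap junction gene Gja1 at -0.57 ± 0.23 and Acsbg1 at -0.52 ± 0.19. Of 7 genes of Purkinje and other cerebellar neurons, 5 were lower (median -0.27, adjusted p = 0.465), and the GABA synthesis gene Gad2 at -0.91 ± 0.22 passed adjusted over the list alone. In the choroid plexus and ependyma list (9 genes, median -0.27, adjusted p = 0.465), Clic6 alone passed adjusted over the list alone, and Otx2 stood at 0.59 ± 0.25. Medians were -0.09 for endothelial and mural cells (15 genes, adjusted p = 0.580), 0.06 for fibroblasts and meninges (14 genes, adjusted p = 0.735) and 0.07 for red blood cells (5 genes, adjusted p = 0.754). Among states, they were -0.08 for hypoxia and glycolysis (15 genes, adjusted p = 0.617), -0.07 for the interferon response (14 genes, adjusted p = 0.465) and 0.00 for immediate early genes (14 genes, adjusted p = 0.845). At the preset correlation, leaving out MyoD+/+ tumour 3 brought the astrocyte (-0.29, adjusted p = 0.000474), Purkinje (-0.49, 0.00933) and interferon (-0.17, 0.00146) lists past the threshold. The choroid plexus list passed without MyoD+/+ tumour 2 (-0.41, adjusted p = 0.00925), and without MyoD+/- tumour 2 the choroid plexus (-0.41, 0.0335), astrocyte (-0.22, 0.0351) and interferon (-0.11, 0.0465) lists did. The astrocyte list also passed with array weights (-0.16, adjusted p = 0.0383) and with a block on Xist signal (-0.11, 0.0424), and the choroid plexus list with median scaling (-0.36, 0.0469). The estimated correlations were 0.45 (astrocyte), 0.39 (Purkinje), 0.47 (interferon) and 0.35 (choroid plexus). With an estimated correlation none of these calls held: the adjusted p was 0.648 without MyoD+/+ tumour 3, 0.884 without MyoD+/+ tumour 2, 0.634 without MyoD+/- tumour 2, 0.813 with array weights, 0.926 with the block on Xist signal and 0.858 with median scaling, and 0.842 for each list with all 5 tumours. The hypoxia gene Ndrg1 differed by -0.76 ± 0.25, the interferon-induced Rsad2 by -0.80 ± 0.27 and the immediate early gene Egr2 by 0.49 ± 0.20.

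Sex-linked transcripts split both genotypes. Xist, the RNA of the inactive X chromosome, stood at 10.58 in MyoD+/+ tumour 1 and 11.06 in MyoD+/- tumour 1, and between 4.57 and 4.64 in the other 3 tumours. The Y-linked Eif2s3y had the reverse pattern, at 4.51 and 4.42 against 7.75 to 8.13. The sex-linked list did not differ between genotypes by the test (4 genes, median -0.21, camera adjusted p = 0.754).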

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

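The block on Xist signal, the oligodendrocyte list without Mbp, Mobp and Mog, and the estimated correlation together with another alternative were chosen after seeing the data. Signal over background limits 253 genes to a bound, since they were below it on every array of 1 group. Median scaling moved the median of all genes by 0.14 (log2), and values under it are relative to that. The Myod1 difference was below 0 under every alternative run (-0.67 to -0.20, adjusted p from 0.748 to 0.999). The oligodendrocyte list median was also below 0 under every alternative run (-0.81 to -0.30). It passed under each of them (without Mbp, Mobp and Mog, -0.57, adjusted p = 0.000214) except camera with the estimated correlation and fry, where the value is the same -0.66. Those tests also ended the calls of the microglia (0.20) and T and B lymphocyte (-0.63) lists. The lymphocyte list did not pass with no filter, which adds undetected members (-0.013), or with the title letters, whose meaning is not given, as a block that pairs tumours across genotypes (-0.57), and it ranged from -0.74 to -0.54 with 1 tumour left out. The microglia list ranged from 0.13 to 0.32 with 1 tumour left out and was 0.11 without background correction. Of the 95 named genes, 60 kept their sign and were over 1.5 times smaller without background correction. With 1 tumour left out, 18 reversed and another 38 moved by over 1.5 times, among them Igf2 (-0.75 to -0.24), Ccnd2 (0.11 to 0.45), Gap43 (-0.56 to -0.18), Cd74 (0.27 to 0.79), Tnfrsf10b (-1.24 to -0.54) and Tnnc2 (0.52 to 3.79). The count of genes was 0 to 1 with 1 tumour left out, 2 with a mean-variance trend and robust estimation, 551 at an unadjusted p under 0.05 and 238 with a fold of at least 1.5 in addition. It was 0 under the other normalizations, filters, probe rules, weights and blocks. Of the other lists, 6 came past the threshold under some alternative (14 values), and 0 of these values passed when the estimated correlation was used under the same alternative (adjusted p from 0.634 to 0.959).

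A total of 81 values of 34 results reversed, none past the threshold (lowest adjusted p 0.0910), and the cause was not tested. Without background correction these were Kdm5c (-0.13) and immediate early genes (-0.0033), and with the authors' processed values Kdm5c (-0.13) and immediate early genes (-0.0035). For Kdm5c, a probe other than the main one stood for the gene in these settings. Median scaling reversed Msc (-0.11) and immediate early genes (-0.011). No filter reversed the fibroblast (-0.0084), interferon (0.011) and immediate early (-0.029) lists, and the strict filter the muscle structural (0.18) and choroid plexus (0.52) lists. The mean of probes reversed Tcf3 (-0.12) and Tcf12 (0.22), and testing every probe the myogenic regulators (0.035) and immediate early (-0.0014) lists. Array weights reversed Mef2c (-0.048), Msc (-0.018), Tcf12 (0.044), Eif2s3y (0.0066), and the hedgehog (-0.0036) and immediate early (-0.050) lists. Title letters as a block reversed Cdh15 (0.076), Smyd1 (0.073), Hba-a1 (-0.25), Fech (0.0039), and the myogenic regulators (0.074) and red blood cell (-0.25) lists. The Xist block reversed the Notch list (-0.0070). With 1 tumour left out, genes ranged as follows: Tcf3 -0.15 to 0.47, Cdh15 -0.54 to 0.19, Mef2c -0.15 to 0.33, Msc -0.10 to 0.10, Tcf12 -0.25 to 0.21, Smyd1 -0.18 to 0.16, Neurod1 -0.083 to 0.90, Notch1 -0.17 to 0.52, Nkd1 -0.10 to 0.67, Lgr5 -0.087 to 0.42, Sox18 -0.11 to 0.92, Ptch1 -0.49 to 0.22, Klf2 -0.82 to 0.032, Hba-a1 -0.75 to 1.51, Slc4a1 -0.22 to 0.50, Fech -0.22 to 0.17, Xist -1.95 to 4.48 and Eif2s3y -2.38 to 1.05. List medians ranged as follows: myogenic regulators -0.16 to 0.074, muscle structural -0.15 to 0.11, hedgehog -0.052 to 0.22, granule neuron precursor -0.060 to 0.095, granule neuron differentiation -0.24 to 0.20, proliferation -0.034 to 0.19, p53 -0.013 to 0.13, Notch -0.17 to 0.17, Wnt -0.087 to 0.26, fibroblast -0.0062 to 0.092, red blood cell -0.75 to 1.32, choroid plexus -0.41 to 0.19, hypoxia -0.22 to 0.028, interferon -0.17 to 0.015 and immediate early -0.32 to 0.33.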

Other observations

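The tests of the brain tissue, lineage and sex explanations, the tests on MyoD+/+ tumour 2 and the chromosome of Zdbf2 were chosen only after the result was seen, and those of sex, skeletal muscle, array signal and granule neurons were also revised after earlier results.

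MyoD+/+ tumour 2 stood apart from the other 4 tumours in a set of genes picked out after their values were seen. In that tumour 57 genes lay more than 1 log2 unit outside the range of the others, 44 of them below it, while the other tumours had 4 to 16 such genes. Tnnc2, a fast-muscle troponin, was not above background there and at least 51.0-fold lower than the mean of the other 4, and Ttr, the thyroxine carrier of the choroid plexus, was 69.4-fold lower. The muscle genes Trim72 (at least 4.15-fold lower), Perm1 (at least 3.53-fold) and Acta1 (5.02-fold) went with them, as did the glutamate transporter of excitatory neurons Slc17a7 (4.95-fold), the growth factor Bdnf (at least 2.16-fold) and the cell cycle inhibitor Cdkn1a (4.09-fold). Fermt1 went the other way, at 8.67 in tumour 2 and between 5.01 and 6.25 elsewhere. So did the ribosomal RNA gene Rn28s1 (7.48, elsewhere 5.59 to 5.97) and Lmo3 (7.23, elsewhere 5.16 to 5.83). The array of tumour 2 also had the lowest array weight (0.63). Of the choroid plexus list, Clic6 was highest in tumour 2 (9.10, elsewhere 6.83 to 8.65) and Otx2 lowest (8.90, elsewhere 8.96 to 9.81). Choroid plexus in the pieces and RNA quality were not tested as sources.

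The values argue against lower signal on that array as the whole source: before normalization, 1445 genes within 1 log2 unit of the Tnnc2 signal had a median deviation of -0.47 in tumour 2, with a 2.5th percentile of -1.24, against -4.01 or lower for Tnnc2 and -4.84 for Ttr. They also argue against skeletal muscle in the other 4 pieces as the source of the whole Tnnc2 gap, provided the muscle probes respond, although Trim72, Perm1 and Acta1 went with it: 7 abundant fast-muscle transcripts, each on its own probe, were higher there than in tumour 2 by a median of 0.26 (bootstrap 95% interval over genes 0.10 to 0.38), and 4 of them (Ckm, Tnni2, Tnnt3 and Myh4) were detected on none of those arrays. Fewer differentiated granule neurons in that tumour cannot be told apart from other sources. Of the 23 granule neuron differentiation genes, Slc17a7 among them, 14 had their lowest level there (median deviation -0.43), but MyoD+/- tumour 1 had a median deviation of -0.33 with Tnnc2 at 10.59 and Ttr at 10.40 (bootstrap 95% interval of the difference -0.38 to 0.13). Genotype does not separate tumour 2 from its group.

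For the lower oligodendrocyte genes in the MyoD+/- tumours, the values argue against sex as the whole cause: each genotype holds 1 tumour with Xist, so sex would need a difference of -3.39 in the list's mean level between tumours with Xist and with Eif2s3y, and that difference was 0.00015 (95% t interval -1.19 to 1.19, n = 2 and 3). With a block on Xist signal the list median was -0.65 (adjusted p = 6.68e-09, with 3.88e-13 to 0.842 over the alternatives run singly, or adjusted p = 0.926 with an estimated correlation). Less surrounding brain in the MyoD+/- pieces could give the pattern and cannot be told apart from it, because the Purkinje and other cerebellar neuron list (7 genes) had a median of -0.27 with an interval from -0.46 to 0.26, which holds 0 and the -0.33 set as the bar, though not a fall as large as -0.66, and has no spread between tumours. Loss of the whole lineage is open as well: 4 other lineage markers (Olig1, Sox10, Pdgfra and Cspg4) had a median of -0.0069 (-0.57 to 0.17) and 10 myelin genes one of -0.78. Of these markers, Cspg4 is also in the endothelial and mural list. A split of the 5 arrays other than the real one, MyoD+/+ tumours 1 and 2 against the rest, gave a median shift of 0.69. That split puts MyoD+/+ tumour 3 with the MyoD+/- tumours. So 2 of the 10 splits were as large as the real -0.66, and 10 splits are too few for a share under 0.05. An effect of the genotype stays open.

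For genes at an unadjusted p under 0.05, 5 of the 10 splits gave as many as the real 551, and the highest of the others gave 1163. That split set MyoD+/+ tumour 2 and MyoD+/- tumour 1, which share the title letter V, against the rest. The next highest (884) set apart MyoD+/+ tumour 3 and MyoD+/- tumour 2, which share the letter P. The meaning of the letters is not given, and the tumours of the first pair also had the lowest medians of the granule neuron differentiation genes (-0.43 and -0.33), so the letters are not singled out. With the letters as a block the real count was 879, and 10 splits are too few for a share under 0.05.

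Gdpd3 and Zdbf2, lower in the MyoD+/- tumours and among the genes with the smallest p, might carry strain variants that travel with the altered Myod1 allele. Zdbf2 lies on chromosome 1 and Myod1 on chromosome 7, which goes against flanking DNA for Zdbf2. Gdpd3 lies on chromosome 7, and of the 306 tested genes between it and Myod1, 19 (6.21%, exact 95% interval 3.78% to 9.53%) had an unadjusted p under 0.05, against 5.23% of the other genes (one-sided Fisher's exact p = 0.259). That interval spans the share of the other genes, so flanking DNA and an effect of MyoD cannot be told apart for Gdpd3. Chance is open as well, since Gdpd3 did not pass over all genes (limma adjusted p = 0.398). Rbbp6 and Klk6, also among the lower genes of smallest p, lie on chromosome 7 too. Flanking DNA was not tested for either of them singly, and the count above covers only the side of Myod1 towards Gdpd3.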
